A study of Drosophila melanogaster with 9 samples.

How the data were processed

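Total RNA from whole dechorionated Drosophila melanogaster embryos was measured on 9 Affymetrix 1-colour arrays, 3 in each of 3 groups. WT embryos carried the marker mutation w. GOF embryos expressed an activated form of Hemipterous (Hep, the kinase that phosphorylates and activates the JNK Basket) in the ectoderm, from a UAS transgene driven by 69B-GAL4. LOF embryos combined the hep alleles rev75 and 1. Per the labels, eggs were aged for about 9 h at 25 °C to stages 13 to 14, when the lateral epidermis closes over the dorsal side. Each collection was checked by in situ hybridisation for dpp and kept if at least 85% of its embryos were at these stages. The RNA samples of a group were prepared independently, and 2 µg of total RNA went into each biotin labelling.

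The deposited values are linear intensities, 1 per probe set and array, which the authors made with RMA, per the submitters' processing notes; version and settings are not given in the sources used here. RMA subtracts background, gives all arrays the same distribution and summarises the probes of a set on the log2 scale, so the authors returned the values to a linear scale before deposit, in whole numbers. The base used for that step is not stated. The deposited intensities ran from 29 to 1331513, and 239 probe sets (1.71%) exceeded 65535, the largest number a 16-bit scanner records, on at least 1 array. Their natural logarithms ran from 3.37 to 14.1, and their base-2 logarithms from 4.86 to 20.34. If the log2 values had been raised with base e, every log2 change given here would be overstated 1.44 times and should be multiplied by 0.693. Summaries of 16-bit intensities should not pass 65535, so the 239 probe sets argue against base 2 unless the values were also rescaled. Whether they were is not given in the sources used here, so base e is favoured but not proven. Directions are not affected, p-values hardly, and fold changes are therefore given under both bases for the main genes. Quartiles were alike on the 9 arrays (medians from 688 to 709), as quantile normalization leaves them.

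The table held 14010 probe sets. With the platform annotation, 12443 had 1 gene, 327 had several, 1196 were unnamed here and 44 were controls. Symbols were compared with the RefSeq gene table of the Release 6 plus ISO1 MT assembly through the gene number: 49 symbols without a match were kept as annotated and the others were current. For the 1209 genes with more than 1 probe set, the set with the highest mean over all 9 arrays stood for the gene, which gave 10844 genes. Genome positions are not printed, because the build behind the probe annotation is not given in the sources used here. Where a gene's own probe sets were tested, 11 of 4039 genes with a changed probe set in GOF had sets that changed in both directions, and 0 of 481 in LOF. These totals include genes with a single set, which cannot disagree. Genes with a changed and an unchanged set were not counted as disagreeing.

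The planned test assumed log2 values as deposited. Since the values were linear, log2(value + 1) was taken, as the plan foresaw. limma (version 3.58.1, R 4.3.3) fitted 1 mean per group to all 9 arrays with lmFit and eBayes (6 residual and 5.39 prior degrees of freedom). GOF against WT, LOF against WT and GOF against LOF were tested two-sided, with a moderated F test over the 3 groups. The threshold was a Benjamini-Hochberg adjusted p of 0.05, with no filter on low values. A gene past it is called changed. The median standard error of a log2 change was 0.11, and 3 arrays per group limit the precision. On simulated arrays with the real means and spreads (10844 genes, 200 of them changed), the GOF against WT step recovered 50.6% of log2 changes of 0.5, 89.1% of 1 and 100% of 2, and 2.5% of its calls were unchanged genes.

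The groups, tests, 29 gene lists, alternatives and the rule for naming genes were fixed before the data were examined, apart from the additions named below. The rule took hep, puc, dpp, scaf and the background markers w and y. For each comparison against WT it took the 10 largest rises and falls among changed genes whose 3 arrays all lay beyond the 3 WT arrays, plus the 2 largest with only a CG or CR number. It added the 5 genes with the largest smaller change in each class changed in both comparisons, and the up to 4 members of each list with the smallest p. This gave 142 genes for GOF and 139 for LOF, from which examples are printed. A few further genes are marked as chosen after their values were seen. Of 742 listed genes, 538 were measured. For 6 ambiguous list entries, the meant gene was settled by name after the table was received, without its values. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over 58 tests (29 lists in 2 comparisons), with an estimated correlation and with fry as alternatives. camera compares a list with all other genes, whereas fry asks whether the members move, on balance, one way.

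Alternatives covered the choice of probe set, a filter removing the 40% of genes with the lowest mean, the arrays in the fit, the variance model, array weights, median centring, cyclic loess and quantile normalization, the replicate number as a block, a fold of at least 1.5, and leaving out each array. Natural logarithms in place of log2, and leaving out WT replicate 2 and GOF replicate 3 together, were added after the data were seen. No 2 arrays held identical values. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. WT replicate 2 had low ratios of 5' to 3' control probe sets (0.14 for actin and 0.113 for eIF-4a, against 0.203 to 0.313 and 0.28 to 0.38 on the other arrays).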

Results

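Gene expression was profiled in whole Drosophila embryos during dorsal closure, the stage at which the epidermal sheets of both flanks move over the amnioserosa and fuse. The study compared embryos with raised and with reduced activity of the Jun N-terminal kinase (JNK) pathway against a reference, to find genes whose level follows JNK activity. Each of the 3 groups had 3 arrays, made from independent RNA samples: WT (genotype w), GOF (activated Hep expressed in the ectoderm) and LOF (hep rev75 over hep 1). The array medians lay between 688 and 709. Arrays of a group correlated at 0.992 to 0.997 across genes, WT with LOF arrays at 0.989 to 0.994, and WT with GOF arrays at 0.962 to 0.97. Values are means of the deposited linear intensities ± SD over n = 3 arrays. Changes are differences of group means of log2(value + 1) with their standard error (SE). They would shrink by the factor 0.693 if the deposited values had been made with base e, which the range of the values favours.

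hep itself, the manipulated gene, was not measurably different in either group. Its main probe set read 3496 ± 586 in WT, 3376 ± 264 in GOF and 3494 ± 170 in LOF (n = 3 each), with log2 changes of -0.04 (SE 0.12, adjusted p = 0.859) and 0.01 (SE 0.12, adjusted p = 0.97) in limma. The second probe set read 1400 ± 180, 960 ± 433 and 1100 ± 267 (log2 changes -0.66 and -0.37, adjusted p over probe sets 0.133 and 0.561). Where these probes lie relative to the transgene and to the lesions of the alleles is not given in the sources used here, so hep checks nothing about the labels, and GOF and LOF stand throughout for the arrays labelled so. The background marker y read 886 ± 48.8 in WT, 1007 ± 58.2 in GOF (adjusted p = 0.27) and 952 ± 162 in LOF (adjusted p = 0.716). w was not analysed here.

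The first comparison asked which genes changed when JNK signalling was activated in the ectoderm. puc, which encodes the phosphatase that inactivates JNK and is induced by it, rose from 2304 ± 270 in WT to 6142 ± 761 in GOF (n = 3 each), a log2 change of 1.41 (SE 0.12, adjusted p = 2.5e-06), which is 2.66-fold, or 1.97-fold if base e was used. dpp, the BMP ligand made in the leading edge of the closing epidermis, rose less, from 516 ± 51 to 640 ± 31.1 (log2 change 0.31, SE 0.09, adjusted p = 0.0191). scaf, a gene for a catalytically inactive protease homologue, has 2 probe sets. One read 1007 ± 167 in WT and 2221 ± 513 in GOF (log2 change 1.13, SE 0.165, adjusted p over probe sets 0.000269, 2.19-fold or 1.72-fold with base e), the other 5318 ± 135 and 6404 ± 394 (log2 change 0.27, SE 0.08, adjusted p = 0.0232). scaf was singled out by the study from these same samples, so its rise is not independent evidence.

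The calls of dpp and of the brighter scaf probe set were not secure. The adjusted p of dpp was 0.0715 without WT replicate 1, 0.0587 without WT replicate 2 and 0.0629 without GOF replicate 3. That of scaf was 0.0672 without WT replicate 1, 0.0526 without WT replicate 3, 0.0973 without GOF replicate 2, 0.0508 with only the GOF and WT arrays in the fit and 0.15 after quantile normalization.

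**Figure D1:**
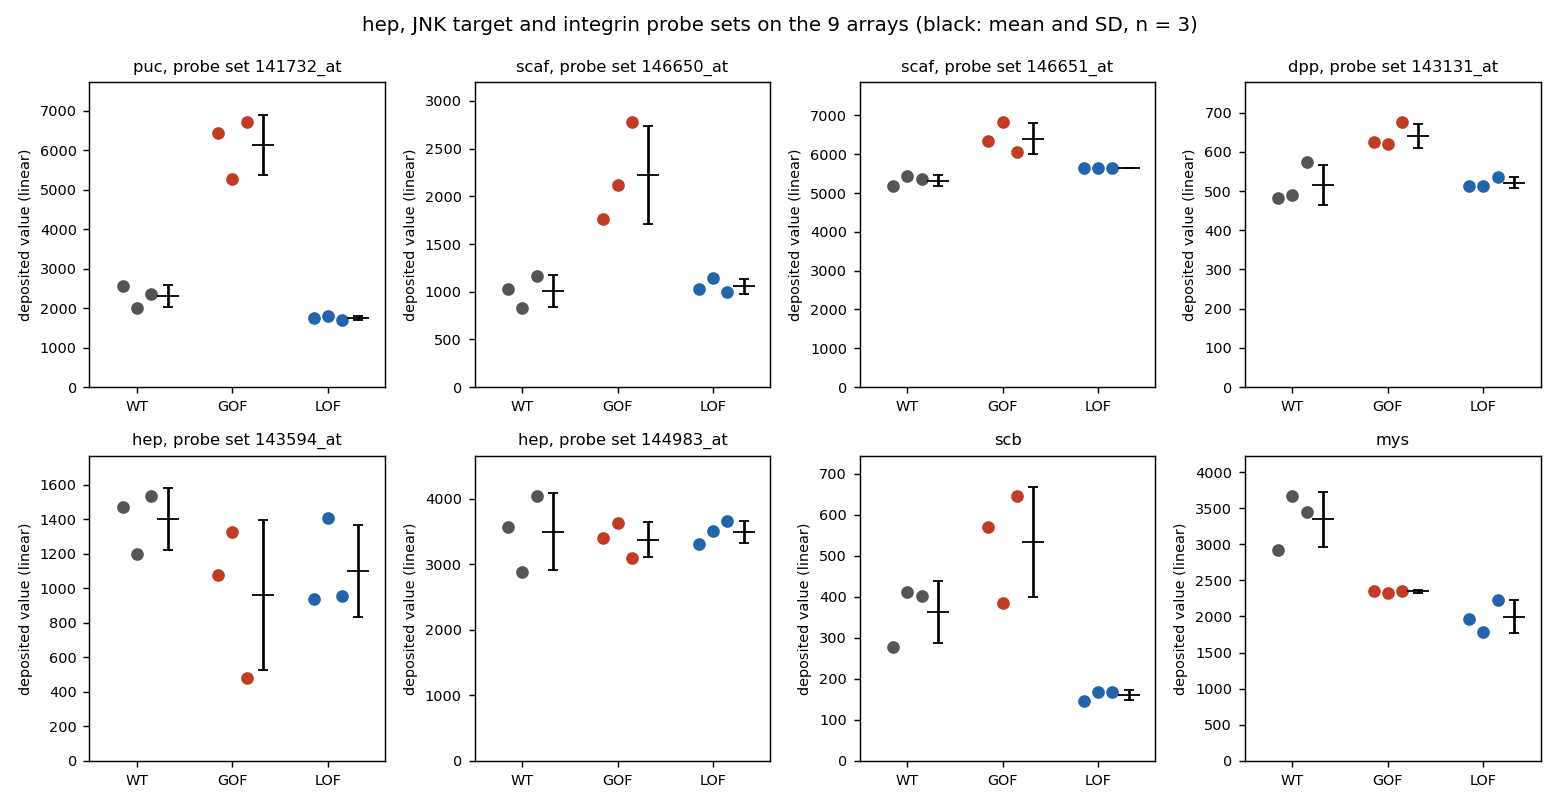
Deposited linear values (y axes, from 0) of puc, scaf, dpp, hep, scb and mys on the 9 arrays, with 1 point per array and the mean and SD of each group of 3 in black beside the points. The GOF arrays of puc lie between 5278 and 6712, above all WT arrays (2016 to 2550), while both hep probe sets overlap among the groups.

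Over all genes, 3980 of 10844 (36.7%) changed in GOF, 1801 up and 2179 down, a majority that cyclic loess turned (2080 up and 1724 down). The rises reached further than the falls: 698 genes rose and 197 fell at least 2-fold, or 355 and 39 if base e was used. The named genes with the largest rises were bcd, the anterior determinant laid down as RNA in the egg (151 ± 37.8 in WT, 6934 ± 4360 in GOF, log2 change 5.21, SE 0.52, adjusted p = 1.24e-05), twe, the Cdc25 phosphatase of meiosis (197 ± 22 to 5036 ± 1180, 4.65), rpk, which encodes an ion channel subunit (75 ± 16.2 to 1784 ± 124, 4.57), and tej, which encodes a Tudor-domain protein of the germ line (141 ± 11.2 to 3399 ± 1310, 4.52). dah, a gene of blastoderm cellularisation (4.36), smg, a regulator of maternal mRNA decay (4.36), swa, needed to place bcd RNA in the oocyte (4.23), the nuclear receptor gene ftz-f1 (4.20) and mol, a maturation factor of dual oxidase (4.20), followed. All of these lay above the 3 WT arrays on all 3 GOF arrays, as did CG15098 (5.15) and CG7730 (4.53).

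Among genes with a name, the deepest fall was that of Tektin-C, a microtubule protein of cilia and flagella (1160 ± 164 to 96 ± 8.02, log2 change -3.57, SE 0.12, adjusted p = 3.59e-09). ImpE2, an ecdysone-inducible gene (43728 ± 12000 to 4462 ± 2230, -3.38), and the prolyl hydroxylase gene PH4alphaSG2 of the salivary gland (3001 ± 247 to 526 ± 52.6, -2.51) followed. Next came mTerf3 (-2.11) and Papss, which makes the sulphate donor for glycan sulphation (-2.02). Osi6 and Osi7 of the Osiris family (-2.01 and -1.999), the chitin-binding protein gene Gasp (-1.96), the nuclear receptor gene Hr4 (-1.93) and the zinc finger gene klu (-1.91) also fell. The Osiris genes varied within groups. Osi6 read 25288 on GOF replicate 3, just below WT replicate 3 (25712), while the other WT arrays read 55020 and 72913. Osi7 read 3273 on WT replicate 3, against 9920 and 9485. LOF replicate 3 was also the lowest of its group, for Osi6 (27213 against 58540 and 51217) and Osi7 (4143 against 7855 and 7152). GOF replicate 3 was instead the highest of its group for both (25288 and 1883). The cause was not tested. Of genes without a name, CG14756 fell by 3.92 and CG13159 by 2.04 on the log2 scale.

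Genes of differentiating ectodermal tissues were lower in GOF as groups. In the epidermis and denticle list, 15 of 23 measured members fell and 0 rose, among them the segment polarity genes en (3772 ± 61.2 to 1263 ± 154, log2 change -1.58) and hh (-1.05) and the apical matrix genes mey (-1.44) and neo (-0.85). The list stood below the other genes in camera (adjusted p = 0.00036), with an adjusted p = 0.224 with an estimated correlation. Of 22 tracheal genes, 13 fell and 3 rose (camera adjusted p = 0.00527, and adjusted p = 0.224 with an estimated correlation). The chitin deacetylase gene verm (-1.22) and uif (-1.45) fell, whereas puc, which the list also holds, rose. In the salivary gland list 11 of 17 fell and 0 rose, with sage (-1.28) and pip (-1.38) besides PH4alphaSG2 and Papss (camera adjusted p = 0.00036, and adjusted p = 0.224 with an estimated correlation). Of 21 septate junction genes, 15 fell, such as cora (-1.13), pck (-0.91) and Gli (-0.90), and 3 rose, with the polarity gene scrib at 1.40 (camera adjusted p = 0.00527, and adjusted p = 0.472 with an estimated correlation). Cuticle and chitin genes fell in 12 of 39 cases and rose in 0, including obst-A (-1.43). That call was the weakest (camera adjusted p = 0.0478, and adjusted p = 0.529 with an estimated correlation) and ended without WT replicate 3 (0.164), without GOF replicate 1 (0.0502), without LOF replicate 3 (0.0528), without the 40% of genes with the lowest mean (0.0909) or with the replicate number as a block (0.0532).

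Amnioserosa genes fell in 11 of 18 cases and rose in 0: the GATA factor gene grn from 1130 ± 79.3 to 471 ± 40.4 (log2 change -1.26), Ance (-1.09), Kr (-1.06) and LanA (-0.96), with a camera adjusted p = 0.00036 and an adjusted p = 0.224 with an estimated correlation. Of 24 hemocyte genes, 11 fell and 0 rose, such as Ppn (-0.87), PPO2 (-0.97) and srp (-0.93) (camera adjusted p = 0.00201, and adjusted p = 0.316 with an estimated correlation). Of 16 glial genes, 10 fell and 0 rose, such as gcm (-1.12), wrapper (-0.77) and ine (-0.71) (camera adjusted p = 0.00253, and adjusted p = 0.224 with an estimated correlation). Notch and Wnt genes fell in 8 of 13 cases, with E(spl)m7-HLH (-0.98), E(spl)m4-BFM (-0.60), nkd (-1.05) and numb (-0.70) (camera adjusted p = 0.00253, and adjusted p = 0.472 with an estimated correlation). In the ecdysone list 11 of 23 fell, such as ImpE2, Hr78 (-1.19) and Hr3 (-1.24), and ftz-f1 alone rose (camera adjusted p = 0.0266, and adjusted p = 0.224 with an estimated correlation).

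Higher as groups stood the detoxification and the germ-line lists. Their median log2 changes were small (0.1 and 0.2) beside their means (0.44 and 0.73), so large rises of some members carry the difference. Of 26 detoxification genes 8 rose and 0 fell, and the 4 named ones were all glutathione S-transferase genes: GstS1 (6378 ± 689 to 34762 ± 3740, log2 change 2.45), GstO2 (1.82), GstE7 (1.69) and GstE1 (1.27) (camera adjusted p = 0.00692, and adjusted p = 0.365 with an estimated correlation). Germ-line genes rose in 9 of 19 cases and fell in 3, with the piRNA pathway genes tej (4.52) and mael (2.94), the mitotic cyclin gene CycB (2.56) and the germ-line innexin gene zpg (1.41) (camera adjusted p = 0.0234, and adjusted p = 0.384 with an estimated correlation). This call ended when the 40% of genes with the lowest mean were left out (adjusted p = 0.529).

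JNK targets known from earlier work did not stand apart from the other genes as a group in camera. Several listed targets, such as rpr and Mmp1, were not measured. Of 21 measured, 7 rose, with puc the clearest, 3 fell (cher -1.15, raw -0.58 and mys -0.51) and 11 were not past the threshold (camera adjusted p = 0.489). The median log2 change of the list was 0.12, and 16.6% of all genes rose in GOF. JNK pathway genes went both ways, with 5 of 21 up, such as the kinase gene mbt (1.01) and Traf6 (0.92), and 10 down, such as Shark (-0.79) and POSH (-0.64) (camera adjusted p = 0.489). So did apoptosis genes, with 5 of 15 up, including the initiator caspase gene Dronc (1.47) and p53 (0.99), and 4 down, including grim (-0.81) and egr (-0.67) (camera adjusted p = 0.909). Of 26 genes of neuroblasts and the cell cycle, 9 rose, with CycB, CycB3 (1.73), fzy (1.47) and aurB (1.23), and 13 fell (camera adjusted p = 0.983, median -0.30 but mean 0.14). Of 26 adhesion and integrin genes, 6 rose, such as stck (1.12), and 11 fell, such as the laminin genes LanA, wb (-0.95) and LanB1 (-0.88) (camera adjusted p = 0.359). Dpp pathway genes fell in 9 of 22 cases, such as gbb (-0.73) and salm (-1.40), and rose in 4 (camera adjusted p = 0.0919).

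Of the other lists, none passed camera in GOF over the 58 tests, but over the 29 GOF tests alone 13 lists passed, muscle being the added one (adjusted p = 0.0431, against 0.0748). Differentiated muscle genes fell in 7 of 22 cases (kon -0.85, rols -0.88) and neuronal genes in 3 of 22 (elav -1.38, fne -1.003, onecut -0.70), with 0 rises in each. Midgut and fat body genes fell in 5 of 24 cases (Apoltp -1.03, GATAe -0.86) and heat shock genes in 4 of 9 (Hsf -0.71, Hsp60A -0.75). Of 18 actin regulators 5 rose (flw 1.16) and 5 fell (cher, Actn -0.75). Of 13 wound response genes 2 rose (krz 1.99) and 4 fell (grh -1.27). Of 18 JAK-STAT and EGFR genes 4 rose (Ptp61F 1.81, Mcm10 2.57, Stat92E 1.098) and 7 fell (spi -1.02). Oxidative phosphorylation genes rose in 6 of 23 cases (ND-42 0.92) and fell in 6 (ATPsynbeta -1.05). Proteases and serpins rose in 5 of 25 (ea 1.68, Spn88Ea 1.58) and fell in 5 (SPE -1.097). Immune genes rose in 2 of 17 (cact 2.04, Mtk 0.45) and fell in 1 (Tep4 -0.50). The calls of Mtk, Tep4 and onecut ended in 3, 5 and 2 settings (adjusted p up to 0.0811, 0.0991 and 0.0616). None of 11 ribosomal protein genes changed in limma, with a median of 0.21.

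Adjusted over the list alone, 14 in place of 9 genes fell in the Dpp pathway list, 15 in place of 11 in the hemocyte list, 13 in place of 11 in the salivary gland list and 16 in place of 15 in the epidermis list. With an estimated correlation 0 of the 29 lists passed in camera for GOF, where 12 passed with the preset one, 17 passed in fry and 14 had an unadjusted p under 0.05. Of the 3980 changed genes, 2288 also changed at least 1.5-fold, or 1302 if base e was used.

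**Figure D2:**
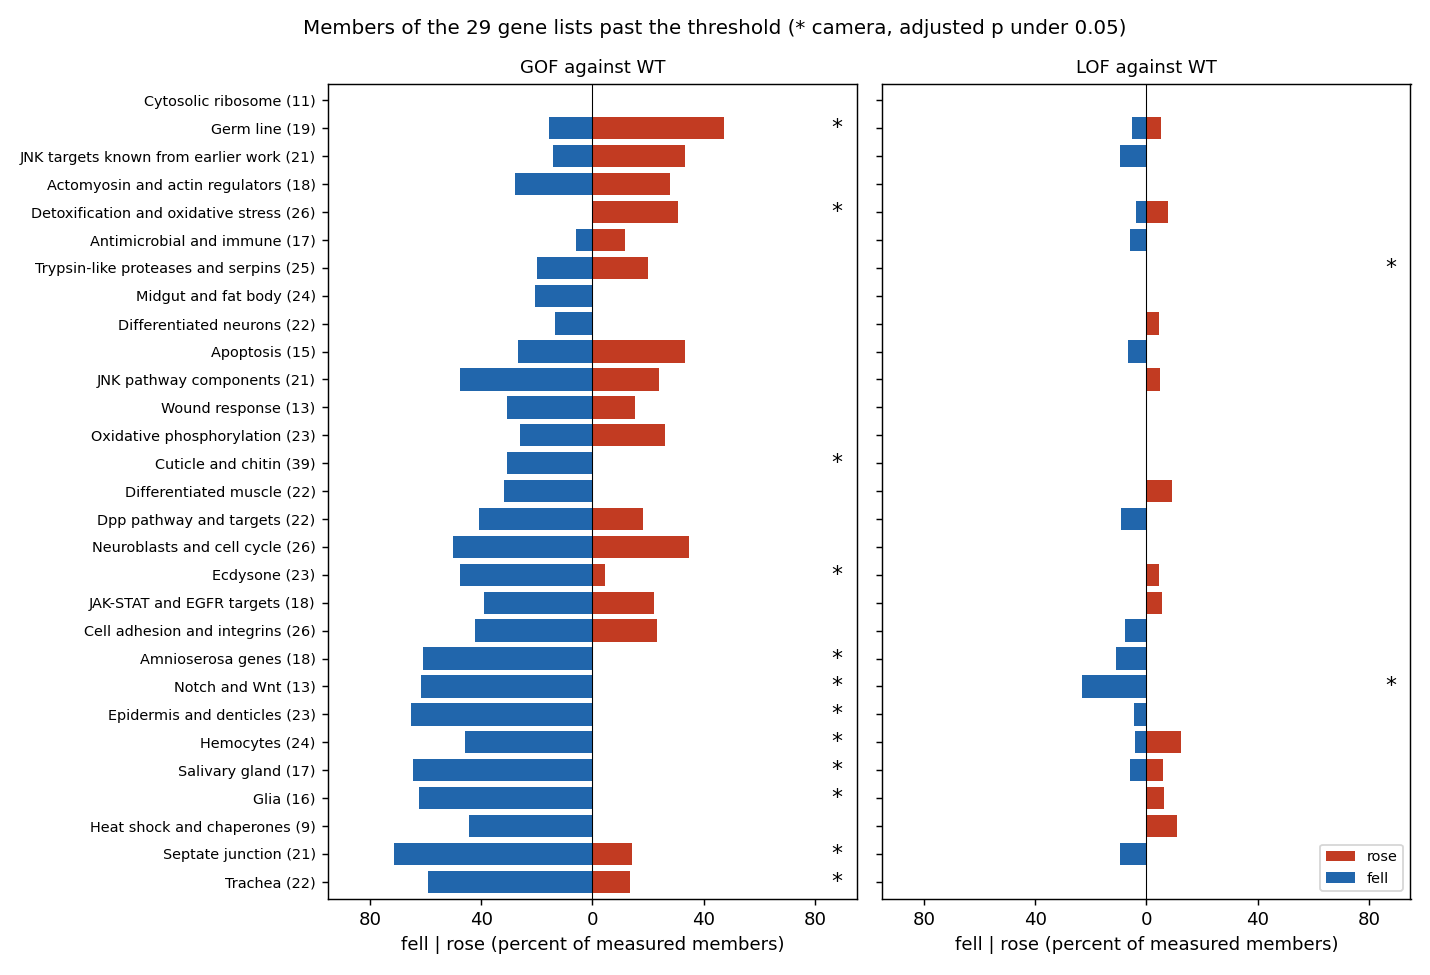
Share of the measured members of each of the 29 lists (number measured in brackets) that rose (red, to the right of 0) or fell (blue, to the left of 0) past the threshold in GOF (left panel) and LOF (right panel), in percent, with lists ordered by their median change in GOF. Asterisks mark the 12 lists in GOF and the 2 in LOF with a camera adjusted p under the threshold.

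The second comparison asked which genes changed when hep function was reduced. Fewer did: 512 of 10844 (4.72%), 147 up and 365 down, of which 19 rose and 20 fell at least 2-fold (1 and 8 if base e was used). puc was 1752 ± 55.7 in LOF against 2304 ± 270 in WT, lower on all 3 arrays but not past the threshold (log2 change -0.39, SE 0.12, adjusted p = 0.0832). dpp (521 ± 13.6, log2 change 0.02, adjusted p = 0.938) and scaf (5647 to 5649 on the 3 arrays for its main probe set, 0.09, adjusted p = 0.601) did not differ measurably from WT. Both integrin genes of the JNK target list fell: scb, an alpha subunit, from 364 ± 75.2 to 160 ± 11.5 (log2 change -1.16, SE 0.19, adjusted p = 0.00769, a 2.23-fold fall, or 1.74-fold with base e) and mys, the main beta subunit, from 3345 ± 383 to 1994 ± 227 (-0.75, SE 0.11, adjusted p = 0.004).

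The deepest falls in LOF were those of Tektin-C (1160 ± 164 to 113 ± 9.85, log2 change -3.34, adjusted p = 7.61e-08), CG8066 (1900 ± 123 to 281 ± 36.7, -2.76), the snoRNA host gene Uhg1 (3096 ± 1300 to 536 ± 93.6, -2.46) and mTerf3 (868 ± 83.4 to 175 ± 9.29, -2.30). The cytochrome P450 gene Cyp12d1-d (-1.77), the deubiquitinase gene trbd (-1.69), the cap-binding protein gene eIF4E3 (-1.55), phu (-1.45), PH4alphaSG2 (-1.28), CG11360 (-1.165), scb (-1.156) and Sid (-1.13) followed. The largest rises of genes with all 3 arrays above WT were those of Pxn, the hemocyte peroxidasin gene (3443 ± 446 to 9609 ± 982, log2 change 1.48, SE 0.14, adjusted p = 0.000263), the maternal thioredoxin gene dhd (159 ± 46.7 to 425 ± 62.6, 1.44), CG14275 (1.37), Ncoa6 (1.36), tara (1.31), CG11883 (1.273), Rdh (1.265), smg (1.19), the transcription factor gene zfh1 (1.16), the RNA-binding protein gene Imp (1.12), bin3 (1.12) and GILT3 (1.11). Of these calls, those of dhd, CG14275, Ncoa6, Imp, bin3 and CG11360 ended when single arrays were left out (adjusted p up to 0.0621, 0.0963, 0.107, 0.192, 0.0839 and 0.0624).

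As groups, Notch and Wnt genes were lower in LOF, with 3 of 13 past the threshold, all of the Enhancer of split complex: E(spl)m4-BFM (8394 ± 655 to 5187 ± 456, log2 change -0.69), E(spl)m7-HLH (-0.77) and E(spl)m5-HLH (-0.59). The camera adjusted p was 0.0234, and the adjusted p = 0.601 with an estimated correlation. Proteases and serpins were higher as a list (median 0.17, camera adjusted p = 0.0294, and adjusted p = 0.45 with an estimated correlation), although 0 of 25 members passed in limma. Both calls rest on adjustment together with the GOF tests, since over the 29 LOF tests alone the smallest adjusted p was 0.0955, and both ended without WT replicate 3 (0.238 and 0.228). The Notch and Wnt call also ended in fry (0.116), without the 40% of genes with the lowest mean (0.107) and without GOF replicate 3 (0.0591). That of the proteases ended without LOF replicate 1 (0.0762), and those of E(spl)m7-HLH and E(spl)m5-HLH in 2 and 4 settings. With an estimated correlation 0 lists passed for LOF, against 4 in fry and 6 with an unadjusted camera p under 0.05.

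Single members of other lists changed in LOF. Among 24 hemocyte genes, Pxn, Ppn (0.58) and PPO2 (0.46) rose and glob1 (-0.91) fell, and among 18 amnioserosa genes Ance (39337 ± 5360 to 21580 ± 2570, -0.86) and pnr (-0.53) fell, which are also the 2 that fell of 22 Dpp pathway genes. The segment polarity gene en (-0.52), the cell death gene grim (-0.59), Rel (-0.39) and the septate junction genes crok (-0.74) and kune (-0.47) fell. The JNK pathway kinase gene slpr (0.59), the muscle genes sls (0.75) and kirre (0.44), brp (0.44), E23 (0.53), simj (0.76) and Hsc70-4 (0.44) rose. In the detoxification list cnc (0.65) and GstD5 (0.78) rose and GstD3 (-0.77) fell. In the germ-line list mael (0.57) rose and Dhc64C (-0.55) fell, and in the salivary gland list PH4alphaEFB (0.50) rose and PH4alphaSG2 fell. None of the actin, cuticle, ribosomal, midgut, cell cycle, oxidative phosphorylation, tracheal and wound response genes listed passed in limma. All of these member calls except those of Pxn, Ance and PH4alphaSG2 ended in at least 1 setting, those of PPO2 and kune in 11 each, and those of sls and Ppn with the mean of all probe sets of a gene (adjusted p 0.442 and 0.721).

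The LOF count depended on single arrays. It was 138 without WT replicate 1, 161 without LOF replicate 2, 260 without LOF replicate 1 and 290 without LOF replicate 3, and 249 genes also changed at least 1.5-fold (77 if base e was used).

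GOF and LOF were then compared directly, so that no WT level enters the difference. Here 4023 genes differed, 1922 higher and 2101 lower in GOF, and 2358 of them at least 1.5-fold (1415 if base e was used). puc was 3.49-fold higher in GOF than in LOF (log2 difference 1.80, SE 0.12, adjusted p over probe sets 5.9e-07), or 2.38-fold with base e. For the first scaf probe set the log2 difference was 1.05 (SE 0.165, adjusted p over probe sets 0.000428). For the brighter set, which stands for scaf, it was 0.18 (SE 0.08, adjusted p over probe sets 0.117) and did not pass. scb differed by 1.70 (SE 0.19, adjusted p = 2.73e-05). Cyclic loess moved the split to 2183 higher and 1435 lower, and median centring to 1983 and 1882.

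Genes whose level moves in opposite directions in GOF and LOF are those the design is aimed at. There were 105: 80 rose in GOF and fell in LOF, where independent lists of these sizes would share 60.6, and 25 fell in GOF and rose in LOF, where they would share 29.5. Among the 80 were Nedd8, the ubiquitin-like modifier (4921 ± 120 in WT, 17012 ± 2020 in GOF, 2914 ± 296 in LOF, log2 changes 1.78 and -0.76), baf, a chromatin-binding protein (1.35 and -0.76), Arl8, a lysosomal GTPase (1.01 and -0.78), CG5986 (0.98 and -0.77) and CG10395 (0.86 and -0.86). scb was also called (0.54, SE 0.19, adjusted p = 0.0435, and -1.16), but its GOF arrays (386 to 646) overlap WT (277 to 412) and its GOF call ended in 9 of 20 settings (adjusted p up to 0.185). Among the 25 were Pxn (-0.71 and 1.48), zfh1 (-0.89 and 1.16), Imp (-0.91 and 1.12), Ppn (-0.87 and 0.58) and CG6966 (-0.69 and 0.58). The LOF calls of CG10395, baf, Imp, CG6966 and Ppn ended in 6, 3, 9, 4 and 1 settings and the GOF call of Imp in 5. All 105 also differed between GOF and LOF, but that difference adds up both opposite changes, so this was fixed in advance and is no further evidence. puc was not among the 105 because its LOF change missed the threshold.

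More genes, 249, changed the same way in both groups: 55 rose (24.4 for independent lists) and 194 fell (73.3). The largest such falls were Tektin-C (-3.57 and -3.34), mTerf3 (-2.11 and -2.30), eIF4E3 (-1.77 and -1.55), phu (-1.86 and -1.45) and Cyp12d1-d (-1.43 and -1.77), and the largest rises dhd (2.35 and 1.44), smg (4.36 and 1.19), GILT3 (1.65 and 1.11), mol (4.20 and 1.05) and the kinase gene Lk6 (1.24 and 0.998). The LOF calls of dhd, mol and Lk6 ended in 3, 3 and 5 settings (adjusted p up to 0.0621, 0.0741 and 0.107). In 173 of the 194 and in 34 of the 55, GOF and LOF levels lay closer to each other than either lay to WT. Called changes of the same direction paired at random gave a share of 78.4% on average. Over 100 draws it ran from 72.7% to 83.5%, so the observed 83.1% lay near the top of the draws. Rises and falls were not set against the draws separately.

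Both comparisons use the same WT arrays. In 100 simulations without any group effect, calls in both comparisons were 0, which the threshold nearly fixes where nothing differs. The simulated changes of the groups correlated at r = 0.5 across genes (observed 0.16) and 66.7% of genes had the same sign (observed 57%). The observed covariance was 0.0242 against 0.00949 simulated, a difference of 0.0147. The 3 WT arrays cannot be split into sets of at least 2, so part of the same-direction excess over independent lists can come from them. For the same reason they can lower the opposite count, so 60.6 and 29.5 are no neutral reference for it. With 1 or 2 WT arrays for GOF and the rest for LOF, the same-direction count was 2.33 to 3.28 times that for independent lists in the 6 ways to do so, and the opposite count 0.39 to 1.97 times. A lone WT array was assumed to vary like the other groups. The count of opposite changes was 21 without WT replicate 1, 26 without LOF replicate 2, 52 without LOF replicate 1, 60 without WT replicate 2, 61 without LOF replicate 3, 162 without GOF replicate 3 and 27 with a fold of at least 1.5 (3 if base e was used). That of changes in the same direction was 76 without WT replicate 1, 83 without LOF replicate 2, 129 without LOF replicate 1, 148 without LOF replicate 3 and 99 with a fold of at least 1.5 (24 if base e was used).

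**Figure D3:**
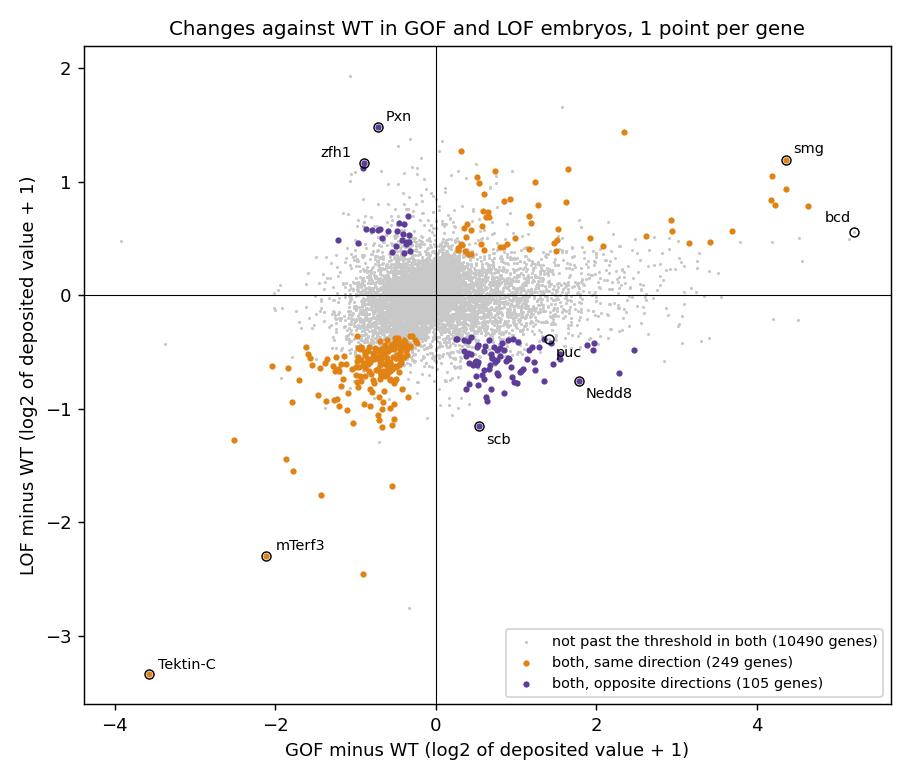
Change against WT in GOF (x axis) and LOF (y axis), both in log2 of the deposited value + 1, with 1 point per gene. The 249 genes changed in the same direction are orange, the 105 changed in opposite directions violet and all others grey, and 9 genes named in the text are circled.

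A moderated F test over the 3 groups found 4446 genes that differed among WT, GOF and LOF (41%), of which 2902 differed at least 1.5-fold between some pair (1708 if base e was used).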

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

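The tests of the maternal, blastoderm and eggshell lists, of the WT stock, of the scale of the GOF arrays and of the shared WT arrays were chosen only after the results they concern were seen. The additional lists of maternal, blastoderm, segmentation and eggshell genes were written after the genes with the largest changes were known.

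Probe sets without a gene name took no part in the comparisons of genes. Of 1196 such probe sets, 358 passed the threshold in GOF, 145 up and 213 down, and 44 passed in LOF, 16 up and 28 down. They were tested as probe sets among all others, and which transcripts they measure is not given in the sources used here.

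Many but not all transcripts laid down in the egg were high in GOF. Of 35 measured genes of a maternal list, 21 rose and 2 fell. The median log2 change was 0.78 (95% interval over genes 0.2 to 1.73). The list was uneven: bcd (5.21) and twe (4.65) rose most, and gcl (-0.91) and cort (-0.4) fell. Others did not pass the threshold, such as nanos (0.04), exu (-0.16), png (0.17), gnu (-0.11) and trk (-0.06). In LOF 5 of the 35 rose, with a median of 0.17. The test as first written took a median above 0.5 over the whole list as fitting an excess of unfertilised or arrested eggs, which 0.78 meets, but it was reworded after that median was seen, because 8 of the 35 genes were known to be high before the list was written. Over the other 27 the median was 0.22 (0.04 to 1.02), with 13 up (48.1% against 16.6% of all genes, Fisher's exact p = 0.00014), 2 down and 0 up in LOF. Of the 35 genes, 10 are also in the germ-line list, which camera had already placed higher in GOF. The Fisher test therefore does not rest on unseen genes alone. It also treats genes as independent, although all were read on the same arrays and can vary together. Its p and the intervals over genes thus do not measure the spread between embryo collections. Unfertilised or arrested eggs remain a possible explanation that the list did not decide. Slower decay of maternal RNA in embryos with activated Hep could give the same values and was not tested. Younger embryos that transcribe blastoderm genes, and ovary or adult tissue, also stay open: medians of -0.09 over 10 blastoderm genes (slam alone rose, by 2.01) and 0.06 over 14 eggshell and yolk genes show no rise, but these lists read 9.66 and 10.57 on the log2 scale in WT, a baseline that would hide a small share.

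Lists of differentiated tissues fell together in GOF: among members above the WT median of all genes, the medians were -0.71 for trachea, -0.69 for glia, -0.68 for epidermis, -0.61 for septate junctions, -0.57 for hemocytes and for salivary gland and -0.44 for muscle, but -0.14 for neurons and -0.07 for midgut and fat body. A shifted scale of the GOF arrays is argued against as the whole source, since the median of the 129 members less that of the other 5293 genes above the WT median was -0.25 to -0.54 on the 3 GOF arrays (-0.02 to 0.02 on the WT arrays), and -0.31 to -0.56 after cyclic loess, under which the midgut and fat body median was 0.03. camera, which compares a list with all other genes, had already placed most of these lists lower. The difference between members and other genes restates that result and is not separate evidence. Dilution by RNA lacking these transcripts, such as egg RNA, would lower every list. The 95% intervals of the neuron list (-1.38 to 0) and of the midgut and fat body list (-0.83 to 0) are too wide to exclude it. The falls of the salivary gland and trachea lists would need 32.6% and 38.9% of such RNA (24% and 28.9% with base e), more than the 15% of embryos outside the stages that the sample labels allow, but RNA per egg, and whether eggs were counted, is not given in the sources used here. Dilution thus stays open beside an effect of JNK activation on these tissues and slower development, neither of which was tested.

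Genes changed the same way in GOF and LOF could reflect differences between the WT stock and the other stocks. In 83.1% of the 249, GOF and LOF levels differed by less than either differed from WT. Called changes paired at random gave 78.4% on average and 72.7% to 83.5% over 100 draws. The observed share lay near the top of the draws but not above all of them, which the rule for this test required. This share thus does not separate a stock difference from an effect of disturbed JNK signalling in either direction, which was not tested. WT replicate 2 is argued against as the whole source, since 201 genes were called without it, 159 of them among the 249 (76 and 74 without WT replicate 1, 208 and 153 without WT replicate 3). Chance of the shared WT arrays stays open: against WT arrays they do not share the count was at least 2.33 times that for independent lists in all 6 ways, but each way leaves a comparison with a lone WT array, and the opposite count reached 1.97 times its own.

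Of 100 regroupings of the 9 arrays, 1, the real one, gave as many genes differing among the groups (4446, the highest other 16), so chance can be excluded as the source of that count. The draw held none of the 9 other regroupings that keep the 3 GOF arrays together, which gave 3151 to 3554 genes when fitted as well, so most of the count shows only that the GOF arrays stand apart. In a separate draw of 100 regroupings, which also assigned the group names, 1, the real one, gave as many opposite changes (105, the highest other 0). Regroupings that mix the GOF arrays leave few calls, so this excludes only that the arrays do not differ by group. It does not show more opposite changes than independent lists share (60.6 and 29.5 against 80 and 25). Because of the shared WT arrays, these numbers for independent lists can be too high a reference for opposite changes. As many genes changed in the same direction as the observed 249 came from 4 of the 100 regroupings of that separate draw, the real one included. The other 3, with up to 2990, put the 3 GOF arrays in the place of WT, which shows that the GOF arrays form the main structure of the data. For each comparison of a pair of groups there are only 10 splits, too few for a share under 0.05: the real splits gave 3980, 512 and 4023 genes and the highest other 0 in each, with 1 of 10 splits reaching the real count.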

How the results depend on the processing

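The natural logarithm, and leaving out WT replicate 2 and GOF replicate 3 together, were chosen after the data were seen. They gave 3982 and 3787 genes in GOF and 510 and 605 in LOF. With a fold of at least 1.5 the counts were 2288 (GOF against WT), 249 (LOF against WT), 2358 (GOF against LOF), 2902 (among the 3 groups), 27 (opposite) and 99 (same direction), by construction lower. Leaving out each array in turn gave 3438 to 3912 for GOF, 138 to 716 for LOF, 3441 to 4124 for GOF against LOF, 3817 to 4384 among the 3 groups, 21 to 162 for opposite and 76 to 316 for same-direction changes. No other setting moved these counts by over 1.5 times. The sign of the hep level turned in some settings. In GOF (-0.04 in the main fit) it was 0.077 after cyclic loess and -0.173 to 0.072 with arrays left out. The mean of its probe sets gave -0.349 there, with the sign kept. In LOF (0.012 in the main fit) it was -0.177 with the mean of its probe sets, -0.062 with array weights, -0.121 without WT replicate 2 and GOF replicate 3, and -0.121 to 0.124 with arrays left out. The hep level never passed the threshold, and the cause of the turns was not tested. Lists called were 11 to 13 in GOF and 1 to 4 in LOF with arrays left out, 0 and 0 with an estimated correlation, and 4 in LOF with fry. Of named genes past the threshold, 127 of 134 in GOF and 24 of 59 in LOF passed in every setting that tested them. There were up to 21 settings, fewer for genes that the filter on low means removed. Sign changes of named genes and lists that passed in neither setting were not counted as reversals. The fit with only a pair of groups gives no value among the 3 groups. The replicate block gave 3993 genes in GOF and 540 in LOF. Same-numbered arrays did not pair clearly: their deviations correlated over 0.1 in 3 of 9 pairs (-0.18 to 0.19), and 3 of 9 arrays correlated best with their own number. For replicates 1, 2 and 3, LOF with WT gave 0.07, 0.19 and 0.11, GOF with WT -0.09, -0.02 and 0.13, and GOF with LOF -0.18, 0.05 and -0.03. No background intensities were analysed here, so what signal over background limits is not known.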

Other observations

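The test of the segmentation list was chosen only after the results were seen. Of 14 measured pair-rule, gap and germ-layer genes, 8 fell and 0 rose in GOF, with a median log2 change of -0.39 (95% interval over genes -0.97 to -0.05), and 0 changed in LOF in limma, with a median of 0. The zinc finger genes sna (-1.07), Kr (-1.06) and kni (-0.90), the homeobox genes ems (-0.97) and oc (-0.57), and odd (-0.87), twi (-0.41) and eve (-0.36) were the 8. The calls of twi and eve ended in 3 and 1 of 21 settings (adjusted p up to 0.0789 and 0.0502). Many of them are expressed again in later tissues, and sna, Kr and kni are also members of the fixed lists.

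Jra, the Drosophila Jun gene and chosen here after its values were seen, read 2009 ± 261 in WT, 3272 ± 455 in GOF and 1569 ± 188 in LOF (n = 3 each). It rose in GOF by a log2 change of 0.70 (SE 0.14, adjusted p = 0.00144 in limma) and did not pass the threshold in LOF (log2 change -0.36, SE 0.14, adjusted p = 0.171). The direct difference of GOF and LOF was 1.06 (SE 0.14, adjusted p = 7.1e-05). Other genes of the JNK pathway list went differently, since in GOF 5 of its 21 genes rose and 10 fell. bsk, the gene of the JNK itself, read 8151 to 9668 on the WT arrays. It was lower on all GOF arrays (3791 to 5874) and on all LOF arrays (5523 to 7132). mys, in contrast to scb, was lower than WT in both groups.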
